A study of Homo sapiens with 12 samples.

How the data were processed

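RNA was measured in tumours labelled as xenografts of Hep3B, a human hepatocellular carcinoma line, from a control group and a group given bufotalin, a bufadienolide of toad venom that belongs to the cardiac glycosides. Total RNA and small RNA were each sequenced in 3 control and 3 bufotalin libraries. Per the labels, RNA was extracted with TRIzol and libraries were made with a NEBNext Ultra kit; dose, time of treatment and strandedness were not given in the sources used here. The labels do not say that replicates are separate animals, so every p-value measures only the spread between these samples, which may be technical.

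The small RNA table deposited by the authors gave a read count per mature miRNA, and beside it the authors gave TPM values. These TPM values equalled the count over the column total, scaled to the same sum in each library, without a length correction (largest difference 4.37e-10). For total RNA, the authors deposited FPKM values per gene for mRNA and FPKM values per transcript for lncRNA, in both cases for features that the authors selected as different on these same samples. The submitters' processing notes named CASAVA 1.8, fastp, HISAT2 2.0.5, featureCounts 1.5.0-p3 and DESeq2 1.20.0 with the GRCh38 build. Which tool made which values, and the rule of selection, were not given in the sources used here. Total RNA depth was unknown: among 686 ratios of FPKM values under 0.1 between library pairs, at most 2 of a pair were equal to 3 decimals, so no steps of whole reads could be seen and no floor or interval was given for FPKM.

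The small RNA table held 1451 features, of which 1380 had human miRNA names and 71 were predictions. Library totals were 4197636, 2053670 and 2034422 counts in control replicates 1, 2 and 3, and 1869893, 3339624 and 2855071 counts in bufotalin replicates 1, 2 and 3. A count of 0 was given a floor of 3 counts per library, or 0.715 to 1.60 CPM (counts scaled to the same sum as TPM). Floors cover counting error only, since reads without molecular identifiers are not independent molecules. Between replicates of a group, chi-square per degree of freedom was 272 to 662, so replicates differed by far more than counting error. In 13 pairs of miRNAs the counts lay within 5% of each other in all 6 libraries (among features with at least 300 counts), 4 of them with identical counts. Their smaller members held 5.61% of all counts, and such pairs cannot be told apart. Of 4988 genes in the mRNA table, 4968 matched the gene reference by Ensembl identifier.

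miRNA counts were compared with edgeR 4.0.16 (TMM normalization, filterByExpr by group, robust quasi-likelihood F test). mRNA values were compared with limma 3.58.1 (trended, robust eBayes) on log2(FPKM + 1) for genes with a mean of at least 0.5 FPKM, and lncRNA values with limma on log2(FPKM + 0.1) for transcripts with a mean of at least 0.1 FPKM. All tests were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Because the mRNA table was selected, each gene list with at least 5 members in it was tested by Fisher's exact test of higher against lower members, compared with the rest of the table. miRNA lists with at least 3 members tested were run with limma's fry and with camera (preset correlation 0.01, and an estimated correlation). fry's directional p asks whether the members move on balance one way, and its mixed p whether they change in either direction. Neither compares a list with other miRNAs. R 4.3.3, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were also used.

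The tests, gene lists, alternatives and the rule for named features were fixed before the data were examined. Named mRNA genes were the 10 largest rises and 10 largest falls among genes past the test with a mean of at least 1 FPKM and no overlap between groups. The same rule took 5 and 5 lncRNA transcripts with a mean of at least 0.1 FPKM. For miRNAs it took up to 10 each way with a mean of at least 10 CPM. The 5 most abundant mRNA genes and miRNAs, and up to 4 members of each list with at least 3 measured members, by smallest p, were added. Any other feature named was chosen after its values were seen.

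The lists of mRNA genes covered hepatocyte and liver tumour markers, DNA replication, mitosis, apoptosis, the unfolded protein and integrated stress response, ferroptosis and glutathione, the sodium pump and ion homeostasis, immediate early genes, hypoxia and glycolysis, epithelial-mesenchymal transition, the Wnt pathway, receptor tyrosine kinases, senescence-associated secretion, telomerase and shelterin, cholesterol synthesis, fatty acid metabolism, interferon-stimulated genes, heat shock proteins, ribosomal proteins, mitochondrially encoded genes, replication-dependent histones, and fibroblast, endothelial, leukocyte, and erythroid and muscle markers. The miRNA lists covered the let-7, miR-17-92, miR-34/449, miR-200, miR-15/16, miR-23/27/24 and miR-29 families or clusters, the miR-371-373 and miR-302/367 clusters, the chromosome 19 and chromosome 14 (DLK1-DIO3) clusters, liver-enriched miRNAs, oncogenic miRNAs of liver cancer, blood-cell miRNAs, and stromal, endothelial and muscle miRNAs.

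On simulated data with known changes, the miRNA test recovered 6 of 44 features at 2-fold and 45 of 49 at 4-fold, and called 1 of 361 unchanged features. The mRNA test recovered 89 of 100 and 99 of 100, with 7 of 4073 unchanged genes called. The lncRNA test recovered 12 of 50 and 21 of 50, with 1 of 365 unchanged transcripts called. A planted miRNA list was found by fry. A planted mRNA list, mitosis with all members higher, ranked 1 by p among the lists in Fisher's exact test. In the real data that list also had all members higher but did not pass (adjusted p 0.0626 by Fisher's exact test). The rank alone does not show that a list of this size can pass there, although this list did with any single bufotalin library left out.

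Alternatives were other scalings, filters and pseudocounts, limma without trend, limma on TPM, DESeq2, a minimum of 2-fold, each replicate left out, and the replicate number as a block. The numbers 1 to 3 were not taken as pairs, because the labels do not say that they mark a shared animal or day. Leaving out miRNAs that share reads, leaving out blood-cell miRNAs, running the gene lists with called genes alone, and quantile normalization of symbol families were added after seeing the data. GC content was not checked because no genome sequence was used here. Levels of genes outside the selected mRNA table were not analysed here. Values of 5 genes and the results of 1 further gene list are not reported here, although counts over genes and lists include them.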

Results

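Tumours labelled as xenografts of Hep3B cells were compared between a control group and a bufotalin-treated group, with 3 total RNA and 3 small RNA libraries in each group. The small RNA libraries held 1869893 to 4197636 counts, and the 5 most abundant miRNAs of each library took 43.8% to 56.4% of them. The mRNA table listed 4988 genes, and 536 transcripts were listed for lncRNA. Their depth was unknown, and the mRNA values added up to 102677 to 121337 FPKM per library. Positions are on GRCh38. Errors after ± are SD over 3 libraries, and SE belongs to the fitted log2 fold change of bufotalin over control.

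The first comparison asked which mRNAs differed in treated tumours. PSG5 (chromosome 19, 43166256 to 43186536), which encodes a pregnancy-specific glycoprotein, rose from 0.062 ± 0.018 to 21.7 ± 3.50 FPKM (log2 fold change 4.41, SE 0.13). SPINK1 (chromosome 5, 147824568 to 147839298), a secreted trypsin inhibitor, rose from 0.743 ± 0.149 to 29.5 ± 6.14 FPKM (4.12, SE 0.15). FST, which encodes the activin antagonist follistatin, rose from 2.91 ± 0.569 to 47.3 ± 3.68 FPKM, and DKK1, a secreted Wnt antagonist, from 3.29 ± 0.724 to 41.9 ± 6.75 FPKM. NOTCH3 (chromosome 19, 15159038 to 15200995), a Notch receptor, fell from 26.6 ± 1.31 to 0.952 ± 0.130 FPKM (-3.82, SE 0.11).

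The transferrin receptor TFRC rose from 94.0 ± 18.7 to 544 ± 26.0 FPKM. The other genes among the 10 largest rises were PSG4, ZNF114, ATP5MG, GPNMB and PSG9. ATP5MG was 7.22 ± 8.04 FPKM in control and 35.3 ± 7.43 FPKM in treated libraries; leaving out control replicate 1 or 3, or bufotalin replicate 2 or 3, ended its call, and its log2 fold change ranged from 2.04 to 3.34 with each library left out in turn. Among the 10 largest falls, HPD, of tyrosine breakdown, fell from 124 ± 7.54 to 14.5 ± 3.61 FPKM (-3.04, SE 0.16). IDH2, the mitochondrial isocitrate dehydrogenase, fell from 19.7 ± 1.15 to 1.54 ± 0.20 FPKM, and MAOB, a monoamine oxidase, from 31.1 ± 2.49 to 2.18 ± 0.421 FPKM. ACY1, UCP2, TMEM141, ALDH3A1, GSTA4 and TMEM37 were the others, with log2 fold changes of -3.52 to -2.83. Reads of the PSG genes may be shared between their near-identical copies, so the split between them is uncertain.

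Among the 5 most abundant genes of the table, MT-CO1, a mitochondrially encoded oxidase subunit, fell from 2424 ± 733 to 657 ± 252 FPKM. ASS1, a urea cycle enzyme, fell from 1914 ± 51.0 to 724 ± 99.99 FPKM. FTH1, the ferritin heavy chain, rose from 740 ± 188 to 1453 ± 41.0 FPKM, and the folate receptor gene FOLR1 from 511 ± 79.9 to 1623 ± 181 FPKM. RPS29, a ribosomal protein gene, rose from 2940 ± 232 to 4410 ± 896 FPKM. The RPS29 call was lost under quantile normalization (log2 fold change 0.28) and without control replicate 1 or 2 or bufotalin replicate 1 or 2 (0.45 to 0.74 over the 6 libraries left out).

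**Figure D1:**
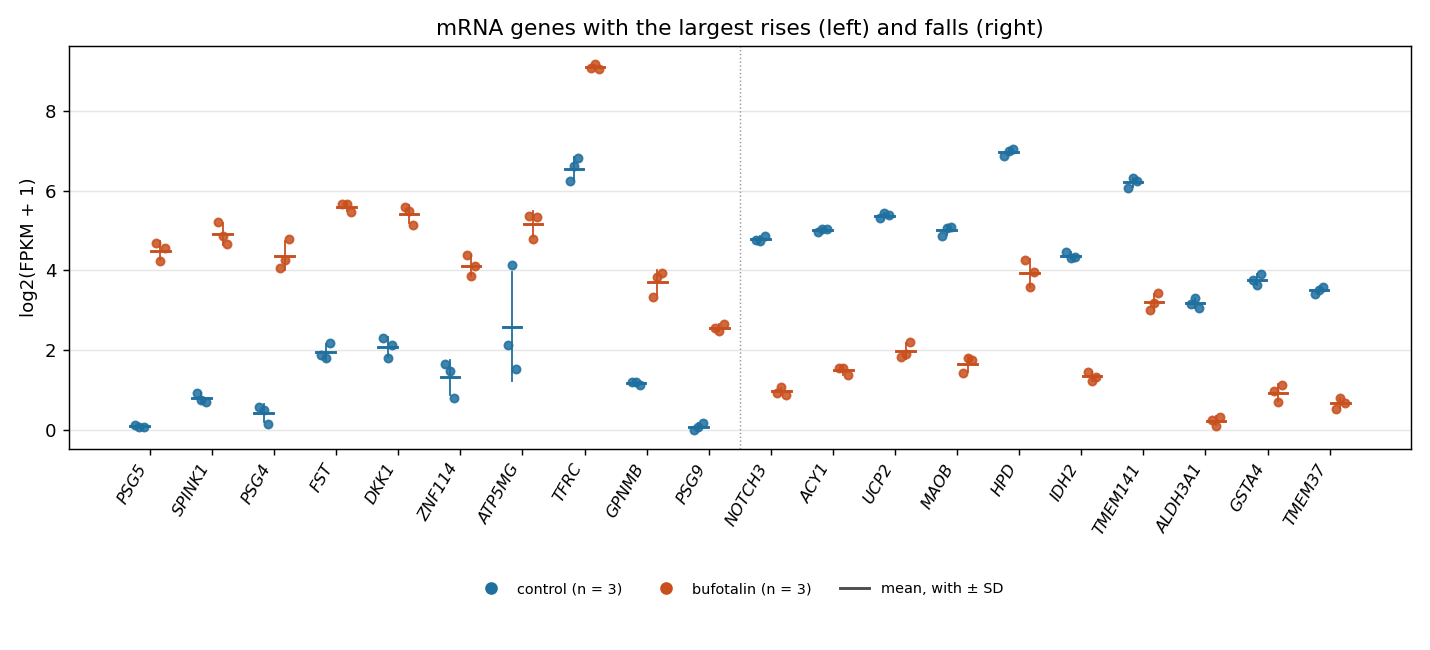
Named mRNA genes of the largest rises and falls: log2(FPKM + 1) in each of 3 control and 3 bufotalin total RNA libraries, with bars for the mean and SD. The groups do not overlap for any gene shown; ATP5MG has the widest spread, with control values of 1.87 to 16.5 FPKM.

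limma with Benjamini-Hochberg adjustment called 3981 of 4273 tested genes, 1894 higher and 2087 lower, and 292 were not called. The authors selected this table on these samples, so the counts are not independent evidence, and 92.4% of its genes having no overlap between groups compares with 10% by chance. Of the called genes, 1410 changed at least 2-fold, 305 higher and 1105 lower. The median log2 fold change of the tested genes was 0.13, and it was 0.31 after scaling to equal medians. It turned below 0 with no FPKM minimum (-0.14) and without bufotalin replicate 1, 2 or 3 (-0.17, -0.06 and -0.27). Fold changes on log2(FPKM + 1) understate genes near 0: PSG5 had 4.41 here and 8.25 with a pseudocount of 0.01, and PSG9 2.49 and 6.87.

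Proliferation genes were split. All 9 listed mitosis genes had higher means, and 7 rose past the test, among them BIRC5, an inhibitor of apoptosis with a mitotic role, from 9.12 ± 3.08 to 26.0 ± 3.30 FPKM, and the proliferation marker MKI67 from 18.4 ± 2.497 to 35.2 ± 8.61 FPKM. BUB1 (log2 fold change 0.52) and CCNB1 (0.42) rose too, but under quantile normalization they had 0.21 and 0.16 and were not called. Of 4 listed DNA replication genes, MCM5 and MCM6 fell (-0.86 and -0.72), PCNA rose (0.38), and UHRF1 had 0.30 without passing, but was called after scaling to equal medians (0.48) and without bufotalin replicate 1 (0.47). The PCNA call was lost under quantile normalization (0.05), with the replicate number as a block, and without control replicate 1 or 2 or bufotalin replicate 2. Of 8 listed replication-dependent histone genes, 5 rose, with HIST1H4H at 458 ± 69.0 in control and 890 ± 185 FPKM in treated libraries. HIST1H3B and HIST1H1E had 0.54 and 0.47, but 0.17 and -0.04 under quantile normalization. Both calls were lost without control replicate 1 or 3 or bufotalin replicate 1, that of HIST1H3B also without bufotalin replicate 2, and that of HIST1H1E also with the replicate block. Histone genes have near-identical copies, so the values of single members are uncertain.

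Stress and death genes went both ways. PPP1R15A, a phosphatase subunit of the integrated stress response, rose from 8.92 ± 1.83 to 43.9 ± 1.67 FPKM, and in its list 6 genes rose and 3 fell, among the latter PDIA4, a disulfide isomerase, from 59.4 ± 2.76 to 29.1 ± 1.42 FPKM. DNAJB9 rose by 0.60 on the log2 scale; CREB3L3 fell (-0.58), but had -0.04 and no call under quantile normalization. Among apoptosis regulators 5 rose and 2 fell. The anti-apoptotic MCL1 rose from 80.2 ± 10.2 to 140 ± 10.3 FPKM, and the pro-apoptotic BAK1 and HRK rose by 0.81 each on the log2 scale, while DIABLO, also pro-apoptotic, fell from 3.47 ± 0.643 to 0.940 ± 0.549 FPKM. Under quantile normalization HRK had 1.45 and DIABLO -0.53 in place of -1.23, both still called. CDKN1A, a cell cycle inhibitor, rose from 31.7 ± 3.65 to 61.8 ± 5.24 FPKM and GDF15, a stress-induced growth factor, from 7.69 ± 1.39 to 17.2 ± 0.441 FPKM, while FDXR (-1.64) and BTG2 (-0.91) fell. Heat shock genes rose in 7 of 9 cases, with HSPA8 from 340 ± 17.8 to 743 ± 95.7 FPKM, HSPH1 at 0.97 and DNAJA1 at 0.90, and fell in 2, with SERPINH1, a collagen chaperone, at -0.81. HSPA1A and HSPA1B are near-identical, so their values are uncertain.

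Genes of iron and redox handling and of the sodium pump mostly rose. HMOX1, the haem-degrading oxygenase, rose from 6.29 ± 0.617 to 15.1 ± 1.17 FPKM and the amino acid transporter subunit SLC3A2 from 159 ± 21.7 to 308 ± 30.6 FPKM. Together with TFRC and FTH1, 6 of the 7 listed ferroptosis and glutathione genes rose, and NQO1, a quinone reductase, fell from 184 ± 21.2 to 110 ± 8.10 FPKM. Cardiac glycosides bind the sodium pump, and its subunit gene ATP1B3 rose from 254 ± 17.02 to 870 ± 279 FPKM. In that list 6 genes rose and 2 fell, with the transporter SLC12A2 at 0.99 and the calcium pump ATP2B4 at -1.45. Of 11 immediate early genes 8 rose and 3 fell. FOSB (1.06) and DUSP5 (1.08) rose, while EGR1 fell from 4.92 ± 0.611 to 0.714 ± 0.286 FPKM and FOS from 47.3 ± 1.40 to 25.9 ± 0.437 FPKM. FOSB had 1.65 and EGR1 -1.15, against -1.80, under quantile normalization.

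Most listed receptor tyrosine kinase, cholesterol, fatty acid and interferon genes were lower, but none of these lists passed the test given below. Of 7 receptor tyrosine kinases and ligands, 6 fell, with ERBB3 from 18.7 ± 1.58 to 4.82 ± 0.199 FPKM, FGFR4 from 13.5 ± 1.74 to 3.87 ± 0.489 FPKM, PDGFA at -0.996 and PDGFB at -1.04 (-0.35 under quantile normalization, still called), and EGFR had 0.41 without passing. Cholesterol synthesis genes fell in 4 of 5 cases, with MSMO1 from 125 ± 20.3 to 45.9 ± 3.71 FPKM, and FDFT1 at -1.30. SREBF2, which encodes the activator of the pathway, rose from 31.4 ± 1.55 to 54.4 ± 0.414 FPKM. Of 8 fatty acid genes 6 fell, with PPARG from 14.7 ± 2.22 to 3.46 ± 0.493 FPKM, CPT2 at -1.50 and ACLY at -0.90, and 2 rose. All 6 listed interferon-stimulated genes fell, with OAS3 from 24.5 ± 1.77 to 10.6 ± 0.439 FPKM, IFIT2 at -0.85 and HLA-C, which shares reads with related genes, at -0.78.

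In the Wnt list 4 genes rose and 3 fell, with GLUL, glutamine synthetase, from 121 ± 2.70 to 46.4 ± 2.14 FPKM, WNT3 at -1.19 (-0.52 under quantile normalization) and NOTUM, a Wnt inactivator, at -0.80 (-0.23 and no call under quantile normalization). Hypoxia and glycolysis genes rose and fell in 4 cases each, with ADM, adrenomedullin, from 12.9 ± 1.55 to 49.5 ± 7.33 FPKM and the aldolase ALDOC from 12.1 ± 3.50 to 1.02 ± 0.139 FPKM, P4HA2 at -1.11 and CA12 at -1.19. Of 8 telomerase and shelterin genes 5 rose, with GAR1 at 0.93 and DKC1 at 0.54 (0.24 and no call under quantile normalization). Among the shelterin genes, TERF2 rose (0.44), and POT1 and ACD fell (-0.92 and -0.87). In the epithelial-mesenchymal list, CDH1 (0.46) and CDH2 (1.02) rose, and SNAI2 (-1.07) and ITGB4 (-1.27) fell. From the senescence list, CDKN2B fell (-0.75) and CDKN1A rose. None of the 22 hepatocyte markers was in the table. The ribosomal list had 1 member there, RPLP1, with 0.38 and no call.

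Markers of other cell types and of RNA quality moved with treatment beside these groups. All 7 listed fibroblast markers fell, with COL6A1 from 28.9 ± 1.55 to 6.43 ± 0.948 FPKM, COL5A1 from 28.9 ± 1.71 to 7.78 ± 0.395 FPKM, TAGLN at -1.54 (-0.87 under quantile normalization) and FBN1 at -1.23. Hepatocellular carcinoma lines may express some of these genes. Whether reads of the host animal contribute was not tested, so these values do not show a change in the number of fibroblasts. The endothelial marker EGFL7 fell (-1.84) and CDH5 rose (0.86), the leukocyte marker CSF1R rose (0.46), and the muscle marker DES fell (-1.49). HBB, of the erythroid list, was 13.4 FPKM in control replicate 3 and 0.367 to 0.552 FPKM in the other libraries. Among mitochondrially encoded genes 1 of 4 fell, MT-CO1; MT-CO2 and MT-CO3 had -1.26 and -1.20 without passing, but both were called without control replicate 3 (-1.75 and -1.73) or bufotalin replicate 3, under quantile normalization, with no FPKM minimum, and with limma without trend. MT-ND6 had 0.31 without passing, was called after scaling to equal medians (0.50), and had -0.17 under quantile normalization. Its listed locus, 1 to 16569 on the mitochondrial chromosome, also covers MT-CO1, MT-CO2 and MT-CO3, so its values may not stand for that gene alone.

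None of the 17 lists tested passed Fisher's exact test of higher against lower members after Benjamini-Hochberg adjustment, and 3 had an unadjusted p under 0.05. The small lists left this test little room to pass. With all members one way, the unadjusted Fisher's exact p was 0.0039 for mitosis, 0.0074 for fibroblast markers and 0.0149 for interferon-stimulated genes. Not passing thus says little about whether the members of a list moved together. The lowest adjusted p was 0.0626, for mitosis (9 of 9 members higher) and for fibroblast markers (7 of 7 lower), followed by 0.0842 for interferon-stimulated genes (6 of 6 lower) and 0.238 for receptor tyrosine kinases and for histones. Mitosis passed (adjusted p 0.0316 to 0.0317 by Fisher's exact test) when any one of the bufotalin libraries was left out, and not in the other settings (0.0561 to 0.0932). Its 9 members were already all higher in the main fit. Without those libraries the median log2 fold change of the tested genes turned below 0 (-0.17, -0.06 and -0.27), which shifted the comparison with the rest of the table. These passes thus cannot be read as a stronger rise of mitosis genes. The remaining lists had adjusted p from 0.354 to 1. Adjusted over the list alone, the number of called genes equalled that over all genes except for histones, with 2 in place of 5. The lists overlap with the authors' selection, so these counts are not independent evidence.

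**Figure D2:**
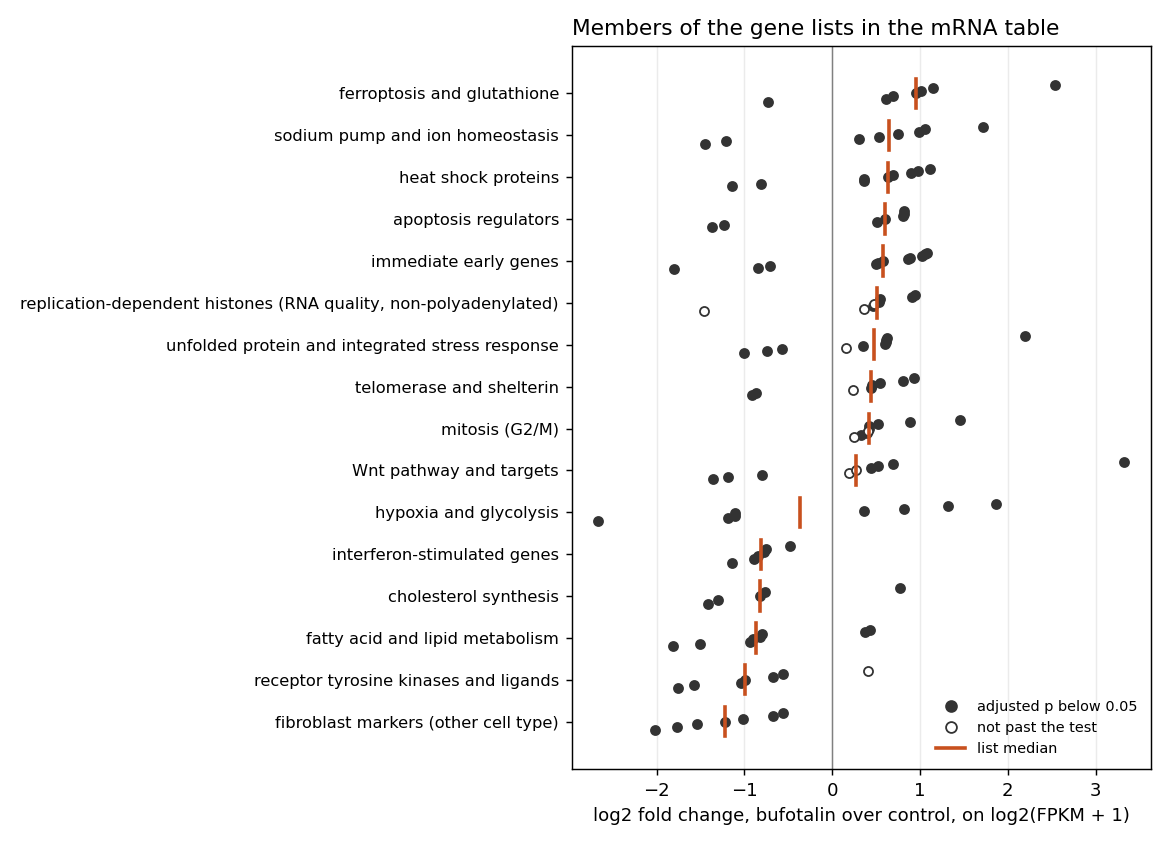
Log2 fold change of bufotalin over control, on log2(FPKM + 1), for each member of gene lists with at least 5 members in the mRNA table, with the median of each list. Filled points passed limma with Benjamini-Hochberg adjustment, and open points did not. Mitosis, ferroptosis and heat shock genes lie mostly to the right and fibroblast, interferon and receptor tyrosine kinase genes to the left; no list passed Fisher's exact test, and the histone genes HIST1H3B and HIST1H1E are not called under quantile normalization, where HIST1H1E turns to -0.04.

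The small RNA comparison asked which miRNAs differed in treated tumours. miR-1246, whose sequence matches part of the U2 small nuclear RNA, rose from 32.4 ± 8.97 to 277 ± 36.0 CPM (log2 fold change 3.10, SE 0.34). miR-425-5p fell from 7822 ± 3162 to 1686 ± 417 CPM (-2.21, SE 0.36), and miR-4454 fell from 636 ± 271 to 100.01 ± 26.5 CPM (-2.67, SE 0.38). miR-210-3p, known for its induction by hypoxia, fell from 81.5 ± 32.8 to 25.8 ± 1.97 CPM. miR-452-5p, of the list of oncogenic miRNAs, fell from 1937 ± 324 to 918 ± 100.08 CPM. The miR-210-3p and miR-452-5p calls ended in 6 and 9 other settings, among them each bufotalin library left out.

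The predicted miRNA novel_633 rose from 1.88 ± 0.122 to 32.0 ± 9.34 CPM. The other named rises were miR-10395-3p, miR-147b-3p, miR-132-5p and the related miR-320b and miR-320c, with log2 fold changes of 1.18 to 2.64; that of miR-10395-3p was 3.94 without control replicate 1. The calls of miR-10395-3p, miR-132-5p, miR-320b and miR-320c ended in 7, 9, 7 and 9 other settings, among them library totals and each bufotalin library left out, and that of miR-147b-3p in 3. Further falls were seen for miR-197-3p (1594 ± 854 to 323 ± 62.1 CPM), miR-574-3p (932 ± 372 to 254 ± 23.7 CPM), both arms of miR-671, miR-874-3p, miR-7974, miR-1247-3p and miR-935, whose calls ended in 2 to 4 settings each. Below 10 CPM, miR-1268a was counted 18, 27 and 48 times in control and 0 times in all 3 treated libraries, at least 11.4-fold lower against the mean per-library floor, or 5.65-fold without control replicate 3. miR-3609 was counted 0, 0 and 1 times in control and 26, 27 and 41 times in treated libraries. The others past the test, chosen after their values were seen, were miR-11401 and miR-514a-3p, which rose, and miR-1180-3p, miR-148a-5p, miR-675-5p and miR-210-5p, which fell. The 5 most abundant miRNAs did not pass: miR-148a-3p had -0.11, miR-21-5p -0.17, let-7i-5p 0.13, let-7f-5p 0.59 and miR-100-5p 0.71.

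**Figure D3:**
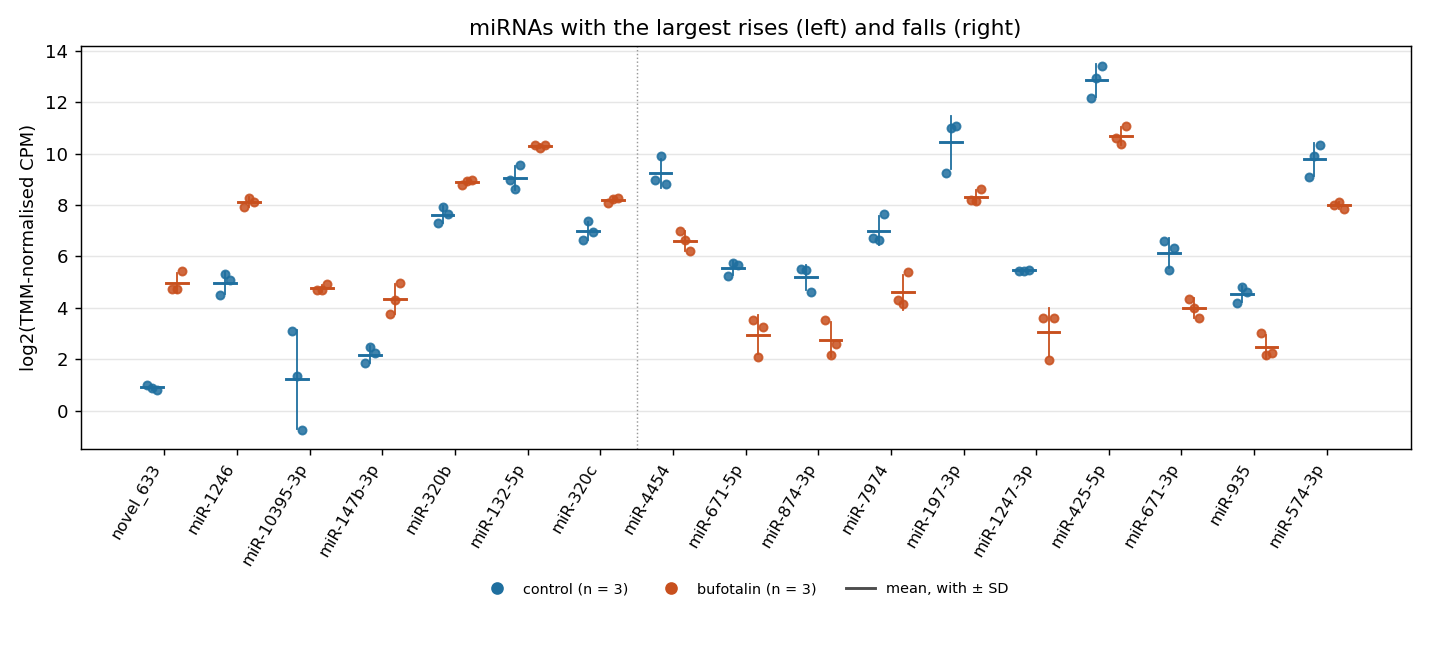
Named miRNAs of the largest rises and falls: log2 of TMM-normalised CPM in each of 3 control and 3 bufotalin small RNA libraries, with bars for the mean and SD. The groups do not overlap for any miRNA shown, and miR-10395-3p has the widest control spread, 0.592 to 8.499 CPM.

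edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 27 of 477 miRNAs, 10 higher and 17 lower, with 124 at an unadjusted p under 0.05; adjusted p was 0.000629 for miR-1246 and 0.0095 for miR-425-5p. The count fell to 13, 8 and 6 without bufotalin replicate 1, 2 and 3, and was 40 without control replicate 1 and 59 with DESeq2, of which 25 were shared. With the replicate number as a block it was 3. Of 19 named miRNAs past the test, miR-1246 and novel_633 passed in every setting; the calls of miR-425-5p and miR-4454 were kept with each library left out in turn but lost with the replicate block (adjusted p 0.0612 for both by edgeR). With library totals in place of TMM, 5 of 21 called miRNAs were higher (23.8%, against 37.0%), and the median log2 fold change was -0.20 against -0.04.

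All 9 let-7 family members had higher means, but none passed the test, with miR-98-5p at 0.68, let-7g-5p at 0.83 (1.26 and called without control replicate 1) and let-7d-5p at 0.47. Among oncogenic miRNAs of liver cancer, miR-210-3p and miR-452-5p fell and 10 of 12 were not called. In the miR-17-92 list, miR-363-3p had 3.45, from 145 CPM in bufotalin replicate 2 and 4.03 to 9.03 CPM elsewhere, and was not called; miR-25-3p had 0.45, and miR-18a-5p and miR-106b-5p had -0.69 and -0.46, which turned to 0.095 and 0.47 without control replicate 2. In the miR-200 list miR-141-3p had 0.99. miR-27a-3p, of the miR-23/27/24 list, had 1.33 with an adjusted p of 0.0510 by edgeR, and was called when adjusted over the list alone and in 6 other settings, among them RLE size factors (0.0420 by edgeR) and DESeq2 (0.0078). From the miR-34 list miR-34a-5p was tested (-1.004, not called), and no member of the miR-371 and miR-302 list was.

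No miRNA list passed limma's fry directional test, and 1 had an unadjusted p under 0.05, the oncogenic list (adjusted p 0.208 by fry, lower on balance; mixed adjusted p 0.0035). Without control replicate 2 that list passed, with an adjusted p of 0.0082 by fry, against 0.182 to 0.572 in the other settings; with camera it did not pass there either (0.269, and 0.681 with an estimated correlation). The other lists had directional adjusted p of 0.371 to 0.806 by fry, and mixed adjusted p of 0.0540 for miR-15/16 and 0.155 to 0.893 for the rest. With camera the lowest adjusted p was 0.142, for let-7, blood-cell and stromal miRNAs, and it was 0.713 with an estimated correlation. These lists passed camera in some other settings: blood-cell and stromal miRNAs without a filter (0.0106 each), let-7 without control replicate 1 (0.0368) and blood-cell miRNAs without bufotalin replicate 3 (0.0421). With an estimated correlation none of these passed (0.643 to 0.778). For the liver-enriched and miR-17-92 lists the median was below 0 (-0.03 and -0.02) while fry gave a higher direction. Adjusted over the list alone, 2 oncogenic miRNAs and 1 of the miR-23/27/24 list were called, and over all miRNAs 2 and 0.

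Blood-cell miRNAs set 1 treated library apart. miR-451a, an erythrocyte miRNA, was at 34779 TPM in bufotalin replicate 2 and at 139 to 404 TPM in the other libraries, and miR-486-5p at 3805 and 92.8 to 202 TPM. Neither was called, and the log2 fold change of miR-486-5p turned from 2.94 to -0.34 without that library. Among stromal and muscle miRNAs, miR-1-3p was at 423 CPM there and 53.5 to 144 CPM elsewhere, and none of the 7 was called. With DESeq2 miR-1-3p and miR-143-3p were (adjusted p 0.0264 and 0.0499), and miR-1-3p also by edgeR without a filter (0.0022). Without the 5 tested blood-cell miRNAs, 30 miRNAs were called by edgeR, among them all 27.

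**Figure D4:**
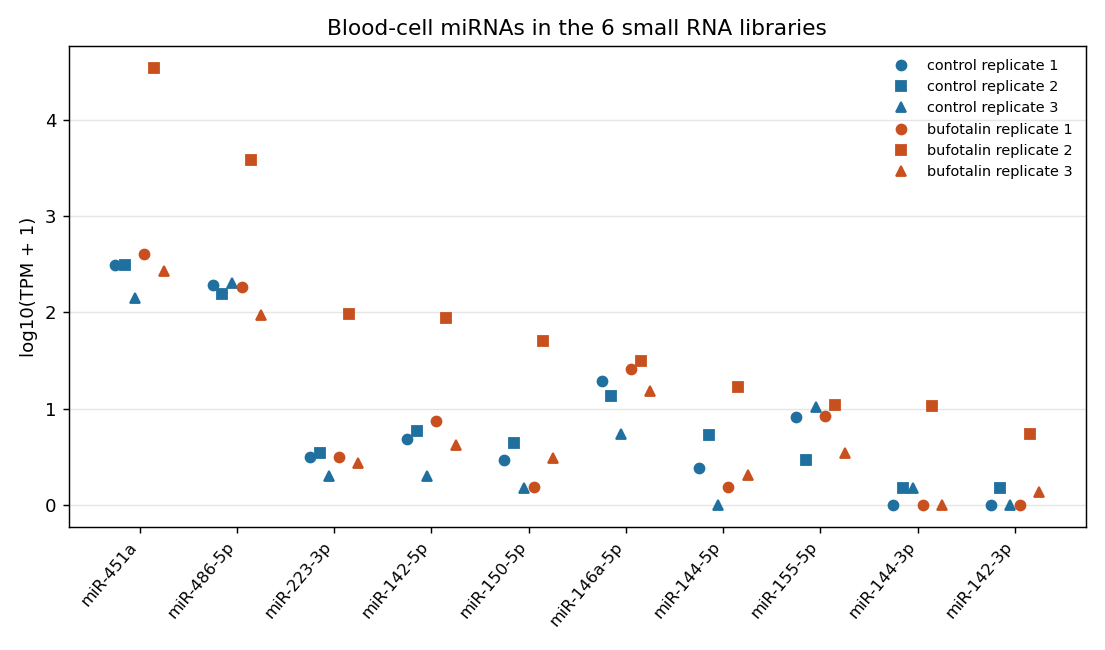
Blood-cell miRNAs in each of the 6 small RNA libraries, as log10(TPM + 1), with control and bufotalin replicates as separate points. Bufotalin replicate 2 has the highest value for all 10 miRNAs, with miR-451a at 34779 TPM there and 139 to 404 TPM in the others.

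The lncRNA comparison asked which transcripts of the lncRNA table differed. MALAT1-202 (chromosome 11, 65497762 to 65506469), a transcript of the abundant nuclear lncRNA MALAT1, fell from 198 ± 77.6 to 1.01 ± 0.172 FPKM (log2 fold change -7.41, SE 0.41). A single transcript does not give the level of the whole gene. IGFL2-AS1-201 (chromosome 19, 46189029 to 46203083), of an antisense lncRNA gene, rose from 0.040 ± 0.069 to 8.37 ± 1.85 FPKM (6.004, SE 0.42). Of the other transcripts of that gene past the test, IGFL2-AS1-212 and IGFL2-AS1-206 rose and IGFL2-AS1-204 fell (-3.09, SE 0.29). DKK1-203, a transcript of the DKK1 gene, rose from 0.038 ± 0.013 to 5.997 ± 0.932 FPKM, in the direction of its gene. The brain-expressed HAR1A-201 fell from 1.34 ± 0.133 to 0.0053 ± 0.0092 FPKM, and LINC01843-201 from 4.03 ± 0.226 to 0.130 ± 0.095 FPKM; these and the other IGFL2-AS1 transcripts were chosen after their values were seen.

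Of the 10 named transcripts, 8 belonged to protein-coding genes. CHD4-227, of a chromatin remodeller gene, rose from 0.091 ± 0.063 to 15.7 ± 10.3 FPKM. IDH3A-208 was listed at 0 in all 3 control libraries and at 16.5, 19.8 and 1.55 FPKM in treated ones, and SDHA-203 at 0 in control and 5.24, 6.13 and 6.47 FPKM in treated ones. MYO10-207 fell from 15.9 ± 1.95 to 0.312 ± 0.266 FPKM, and PATJ-216 from 9.93 ± 5.91 to 0.0009 ± 0.00078 FPKM. FDPS-211 was at 11.2, 12.6 and 5.29 FPKM in control and SELENBP1-212 at 7.40, 1.54 and 10.3 FPKM, and both were listed at 0 in all treated libraries. Of 132 transcripts past the test whose gene also passed in the mRNA table, 125 (94.7%) had the direction of their gene. The 7 others were CUL9-203, L3MBTL2-206, LARP1B-208, PKN3-203, RAB10-204, SCOC-OT1 and TRAF4-212. Reads of a transcript and its gene overlap, and without strand information antisense transcripts cannot be told apart from genes on the other strand.

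**Figure D5:**
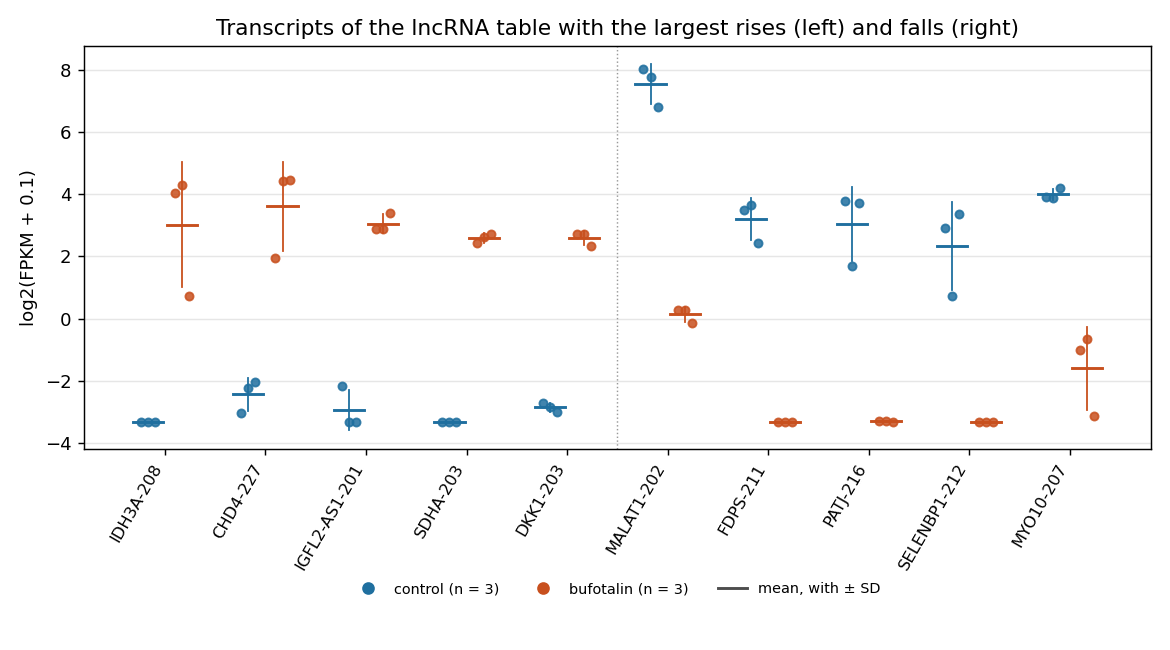
Named transcripts of the lncRNA table: log2(FPKM + 0.1) in each of 3 control and 3 bufotalin total RNA libraries, with bars for the mean and SD. MALAT1-202 lies at 112 to 263 FPKM in control and 0.808 to 1.11 FPKM in treated libraries.

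limma with Benjamini-Hochberg adjustment called 341 of 465 transcripts, 136 higher and 205 lower. Those of lncRNA genes were 12 higher and 31 lower among 63 tested, and those of protein-coding genes 89 higher and 125 lower among 295. The authors selected the table on these samples, so these counts are not independent evidence; 81.2% of its transcripts had no overlap between groups, against 10% by chance. The median log2 fold change was -1.74, -1.17 under quantile normalization, and -0.35 and -3.98 with pseudocounts of 1 and 0.01; among transcripts with a mean of at least 0.5 FPKM it was 2.25, in the other direction. Fold changes of transcripts near 0 depend on the pseudocount: SDHA-203 had 5.91 on this scale and 2.79 with a pseudocount of 1. Leaving out 1 library moved 5 named values most: CHD4-227 to 6.89 without bufotalin replicate 1, IDH3A-208 to 5.71 without replicate 2 and 7.50 without replicate 3, MYO10-207 to -4.84 without replicate 3, and PATJ-216 and SELENBP1-212 to -7.06 and -6.47 without control replicate 2. A minimum of 0.5 FPKM left 110 of 157 transcripts called, 54 higher and 56 lower.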

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

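The alternatives reported here were planned, except leaving out miRNAs with shared reads, leaving out blood-cell miRNAs, running the gene lists with called genes alone and quantile normalization of symbol families, which were chosen after seeing the data. The depth of the FPKM values was unknown. Where a value below changed, the cause was not tested, except that a 2-fold minimum and a higher FPKM minimum leave fewer features by construction. Scaling the lncRNA table to equal medians could not give a value, because the median of the treated libraries was 0.

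The miRNA count of 27 became 59 with DESeq2, where 1021 miRNAs had no adjusted p, and 6 to 40 with each library left out: 13, 8 and 6 without bufotalin replicates 1, 2 and 3, and 40, 23 and 32 without control replicates 1, 2 and 3. A group left with fewer libraries was assumed to vary like the other. Settings other than these and the replicate block gave 19 to 40. The mRNA count of 3981 became 1410 with a 2-fold minimum, 3728 to 3876 with a library left out, and 3256 to 4456 in other settings; all 1410 were among the 3981. The lncRNA count of 341 became 110 with a mean of at least 0.5 FPKM, 322 to 340 with a library left out, and 307 to 403 in other settings. Gene lists past the test were 0 to 1 with a library left out (mitosis, without any one bufotalin replicate), and miRNA lists by fry 0 to 1 (oncogenic miRNAs, without control replicate 2); both were 0 in all other settings run. By camera with the preset correlation, 2 miRNA lists passed without a filter and 1 each without control replicate 1 and bufotalin replicate 3. With quantile normalization, MT-ND6 reversed to -0.17 and HIST1H1E to -0.036. With library totals, miR-23a-3p reversed to -0.0054 and miR-127-3p to -0.18.

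With each library left out, the log2 fold change of these uncalled miRNAs changed sign: miR-148a-3p (-0.52 to 0.51), let-7i-5p (-0.19 to 0.37), miR-18a-5p (-1.01 to 0.095), miR-106b-5p (-0.85 to 0.47), miR-122-5p (-1.48 to 0.51), miR-23a-3p (-0.057 to 0.35), miR-29c-3p (-0.74 to 0.71), miR-519a-3p (-0.69 to 0.33), miR-379-5p (-0.071 to 0.97), miR-127-3p (-0.69 to 1.45) and miR-486-5p (-0.34 to 3.50). All 130 values of named lncRNA transcripts, 70 in other settings and 60 with a library left out, kept direction and call. Of 811 values of named mRNA genes under other settings, 790 kept both, 10 lost the call, 9 gained it and 2 reversed; with a library left out, 581 of 605 kept both, 18 lost the call and 6 gained it. Of 654 miRNA values under other settings, 610 kept both, 31 lost the call, 9 gained it and 4 reversed; with a library left out, 340 of 402 kept both, 45 lost the call, 2 gained it and 15 reversed.

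With the replicate number as a replicate block, 3 miRNAs, 3957 mRNA genes, 335 lncRNA transcripts and no list were called, and miR-148a-3p reversed to 0.019 and miR-29c-3p to 0.032. The block uses up residual degrees of freedom. Correlations of same-numbered libraries, after removing group means, were 0.13, 0.03 and 0.36 for miRNAs. They were -0.02, 0.03 and -0.05 for mRNAs, and 0.01, -0.0017 and -0.01 for lncRNAs. For miRNAs, control replicate 3 had 0.36 with its own number and at most -0.18 with the other bufotalin libraries. Pairing of the small RNA libraries numbered 3 thus stays open. Not every library correlated best with its own number.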

Other observations

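The tests of histone RNA capture, S phase, blood miRNAs and other splits of the libraries were chosen only after the result was seen; those of histone scaling and of miRNA host genes were written before, although HIST1H1E alone had been seen under quantile normalization.

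A grouping of the mRNA table by gene symbol, made after seeing the data, showed families that the lists had not covered. All 5 PSG genes in the table rose, among them PSG1 from 0.014 ± 0.013 to 2.75 ± 1.07 FPKM; PSG2 was listed at 0 in all control libraries and at 4.27, 2.53 and 3.04 FPKM in treated ones. CGA, the alpha subunit of the glycoprotein hormones, rose from 78.9 ± 4.34 to 396 ± 112 FPKM. Among epithelial keratins, KRT17 rose from 70.0 ± 4.66 to 132 ± 19.9 FPKM and KRT7 fell from 102 ± 5.76 to 50.8 ± 8.87 FPKM. Of 31 symbol families with at least 10 genes, HIST alone passed Fisher's exact test of higher against lower after Benjamini-Hochberg adjustment. RNA-binding RBM genes (12 of 14 higher, adjusted p 0.199 by Fisher's exact test) and collagens (3 of 12 higher, 0.395) did not, although RBM passed under quantile normalization (0.0302), where 2 families did. Of 23 chromosomes, chromosome 19, which holds the PSG genes, passed Fisher's exact test, with 192 of 320 genes higher (60%, adjusted p 0.0087), and no other did. Genes of a family or chromosome are not independent replicates, so p-values of these tests may be too small. The liver-secreted APOE, VTN and C3 reached at most 2.54, 6.77 and 4.71 FPKM, while FOLR1 lay at 418 to 1761 FPKM. APOE, VTN and C3 were picked after their values were seen. HPD and ASS1, enzymes that also work in liver, had the much higher control levels given above. The 22 hepatocyte markers were absent from the selected table, so their levels could not be read. As Hep3B is a liver line, the levels of APOE, VTN, C3 and FOLR1 leave the labelled identity of the cells in doubt. What every value here stands for is in doubt with it. No reference level of APOE, VTN, C3 or FOLR1 in Hep3B cells was compared here, so the doubt itself was not tested. Neither another cell line nor RNA of the host animal was tested as a reason for these levels, since neither mouse sequence nor genotype was used here.

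Of 25 genes named HIST, 24 had higher means in treated libraries and 13 rose past the limma test (Fisher's exact p 1.5e-06, adjusted p 4.6e-05 over 31 families). Fisher's exact test takes genes as independent, which near-identical copies measured in the same libraries are not, so its p-values here may be too small. Capture of more RNA without poly(A) tails could not be decided. Of 5 replacement histone genes, whose mRNAs have such tails, 4 rose past the limma test and none fell. With all 4 called genes higher, Fisher's exact p against the other called genes was 0.0511. No split of 4 called genes could have given a smaller p, so this test could not pass. MALAT1-202, which lacks a tail, fell, but it is a single transcript of its gene. Genes that did not change were largely left out of the selected table, and H2AFX (1.03), which makes both kinds of mRNA, was not counted. Scaling of the FPKM values could not be decided either: under quantile normalization 21 genes stayed higher and Fisher's exact test still passed (adjusted p 0.0302), but the median log2 fold change of the 25 went from 0.55 to 0.18 and 6 in place of 13 rose past the limma test. The 21 lay above the bound of 20 set beforehand by less than its binomial SD of 1.83, a margin asked for only after the value was seen. Scaling to equal medians, also planned as a test, raised nearly all genes alike and decides nothing. More cells in S phase could not be decided, since 1 listed S phase gene rose and 2 fell. Shared reads between copies were not tested and stay open, as does an effect of treatment on histone mRNA.

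All 10 blood-cell miRNAs with at least 10 counts had their highest deposited TPM value in bufotalin small RNA replicate 2, and 9 did in TMM-normalised CPM, where miR-155-5p was higher in control replicate 3. This is consistent with blood RNA in that library. In that library miR-451a lay 104-fold above the mean of the other treated libraries, so the treated libraries did not share its high level. That ratio restates the pattern that prompted the test, and it cannot exclude an effect of treatment in that library alone. Deeper sequencing was argued against by the 112-fold excess of miR-451a over the deeper control replicate 1. miR-146a-5p and miR-155-5p, which other cells also express, exceeded the other treated libraries by 1.54-fold and 1.99-fold. In the total RNA libraries HBB was highest in control replicate 3 (13.4 FPKM). Whether the blood was of the host animal was not tested.

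A further hypothesis was that miRNAs follow the direction of the gene that holds them. Of 72 miRNA genes inside genes of the mRNA table, 68 had a host past the test. Across these genes, which are not independent replicates, Spearman's rho was 0.20 (permutation p 0.112, 100000 resamples). Of 28 pairs with an unadjusted miRNA p under 0.05, 17 shared the sign of the host (Fisher's exact p 0.677), so the hypothesis may hold for some pairs but was not shown. Examples that shared the sign were miR-425-5p (-2.21) in DALRD3 (-1.34), miR-574-3p (-1.87) in FAM114A1 (-1.69) and miR-1180-3p (-1.33) in B9D1 (-2.46). The sign was not shared by miR-1908-5p (-1.80) in FADS2 (1.29). miR-191-5p, which also lies in DALRD3, had -0.26 without passing the test. The match of names to miRNA genes was corrected for miRNAs with numbered gene copies after a first value had been seen, and strand was not used.

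The 6 libraries of each kind can be split 10 ways into 3 and 3, too few for a share under 0.05. The real split gave 27 miRNAs, 3981 mRNA genes and 341 lncRNA transcripts, each matched by 1 of 10 splits, the real one, and the highest of the other splits was 0 for each. The authors selected the mRNA and lncRNA features on the real split, and every other split mixes the groups. For these features the counts of 0 were thus largely fixed in advance and give no support. For gene lists the real split gave 0 and the highest other 2, and for miRNA lists 0 and 0, so that 10 of 10 splits were as large.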
